A study of Mus musculus with 18 samples.

How the data were processed

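RNA was measured in the striatum and the substantia nigra of C57BL6 mice, with 9 libraries per tissue and 18 in all. Per the labels' protocols, RNA was extracted with a column kit and made into stranded, poly(A)-selected Illumina libraries. Per the submitters' processing notes, FastQC 0.11.7, Trim Galore 0.38, STAR 2.7.3a and Cufflinks were used with the mouse genome build GRCm38. The notes give neither the order of these tools nor the version of Cufflinks, and the setting that decided how reads on each strand were counted is not given in the sources used here.

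The authors deposited 1 table per tissue, and the unit of each column was taken from the headers and checked against the values. Per the file headers, the authors deposited raw read counts per gene, which are whole numbers that sum to a different total in each library. The authors also deposited FPKM values, which are scaled by gene length and library total, and TPM values, which add up to the same total in every library. The deposited tables further hold normalized values on a log2 scale with a log2 mean per group, whose method is not given in the sources used here. For each pair of groups the authors deposited a signed linear fold change, a standard error on the log2 scale, a test statistic (a score with no fixed range), an unadjusted p-value and a Benjamini-Hochberg adjusted p-value. The test behind these comparison columns is not given in the sources used here. Each table lists only genes with a count of at least 1 in all 9 of its libraries, so a gene silent in a single library is not analysed here. TPM values and the authors' group means were not used, and 0 columns belonged to samples of another series.

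Groups were taken from the sample labels: phosphate-buffered saline (PBS) in the striatum with PBS by injection, 6-hydroxydopamine (6-OHDA) with PBS, and 6-OHDA with TUG469, with 3 libraries per group and tissue. The design had assumed FPKM values with limma as the test, and stated that edgeR would take its place if raw counts were given. Since counts were given, the main test was the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, and limma 3.58.1 on log2(FPKM + 1) became an alternative. Genes were kept by filterByExpr with a minimum count of 10 and a minimum total of 15, which left 19115 of 20257 genes in striatum and 19686 of 20897 in nigra. Libraries were scaled by TMM factors, and the 9 libraries of a tissue entered 1 fit with a mean per group and no covariate. The biological coefficient of variation was 0.161 in striatum and 0.135 in nigra. P-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Log2 fold changes and their standard errors (SE) come from this fit. Levels are CPM, counts scaled to a common library total with TMM factors, given as mean ± SD over the 3 libraries of a group. The change after 6-OHDA was compared between tissues as an interaction over 18749 genes in 1 edgeR fit of all 18 libraries, with 6 group means.

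Gene lists numbered 32 and covered the dopamine system, neuronal classes of striatum and nigra, glia, vessels, blood, brain regions next to the dissected tissue, inflammation, and stress and energy pathways. They were tested with limma's camera at its preset correlation of 0.01 between genes, adjusted over the lists of a tissue and comparison. Camera with an estimated correlation and fry were run beside it. Lists needed at least 3 tested members. Camera asks whether a list moved relative to all other genes. Fry asks whether its genes moved, on balance, in 1 direction. Within each list, gene p-values were also adjusted over the list alone. Groups, tests, lists, most alternatives and the rule for named genes were fixed before the data were examined.

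Genes were named by a rule with 3 parts. The study's own genes (Th, Slc6a3, Slc18a2, Ddc, Ffar1, Nlrp3, Pycard, Casp1, Il1b, Il18, Gfap and Aif1) were named whatever their result. Next came the 10 largest rises and 10 largest falls among genes past the adjusted threshold with a group mean of at least 1 FPKM and groups that did not overlap. Where fewer than 5 genes passed in a direction, the 5 with the smallest unadjusted p and groups that did not overlap took their place. Up to 4 members with the smallest p were named per list that passed a test or held a member past the threshold adjusted over the list alone. Predicted genes were passed over in the second part. The rule had been written for the 6-OHDA and TUG469 comparisons, and its use for TUG469-treated against PBS mice was added later. One gene taken by the rule in that comparison is not reported here. Genes carry NCBI Gene identifiers, and coordinates are those of a RefSeq gene table on GRCm38, to which 20207 of 20257 identifiers in striatum and 20844 of 20897 in nigra matched. Every row carried a gene name.

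The procedure was tested on simulated counts drawn from the means and library sizes of the real libraries, with 200 genes changed by a known amount. The changed genes were taken from those above a minimum mean level, and each gene was drawn independently. The shares therefore do not cover weakly expressed genes or variation that libraries share across genes. With 200 genes changed at once, the adjusted threshold is also easier to pass than where few genes differ. The shares thus overstate what could be recovered in comparisons with few calls. In striatum, the test recovered 84% of genes changed 2-fold for the 6-OHDA comparison, 75% for TUG469 against 6-OHDA and 83% for TUG469 against PBS. In nigra the shares were 87%, 89% and 88%. Of genes changed 4-fold, it recovered 98%, 93% and 98% in striatum and 100%, 98% and 100% in nigra, with 6 to 20 unchanged genes called per comparison. The interaction between tissues was simulated on 18749 genes, where 93% of genes changed 4-fold were recovered. With a length trend planted in the nigral libraries for TUG469 against PBS, 4656 unchanged genes were called as counted and 11 once the trend was removed.

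Replicate libraries were compared for duplicates by a chi-square statistic per degree of freedom, which ranged from 9.2 to 59.8, so no pair agreed within sampling noise. The labels do not say that libraries came from separate animals. P-values therefore measure the spread between these libraries, and part of that spread may be technical. With 3 libraries against 3, an exact permutation test of 1 gene cannot go below 0.1, so single genes were tested only within the models fitted across all genes. A prior count of 2 was used for log2 CPM levels, which were averaged over the members of a list to give a level per library.

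The alternatives were no filter on low counts, limma on log2(FPKM + 1) with at least 1 FPKM in 3 libraries, a pseudocount of 0.1, quantile normalization, limma on the authors' log2 values, DESeq2 1.42.0, a fit of only the compared groups, the replicate number as a block, and each library left out in turn. Added after the values were seen were RLE scaling factors, a marker level of a neighbouring brain region as a covariate, the removal of a trend with transcript length and GC content (transcripts of a GENCODE annotation on GRCm38), and the striatum without the library of each group lowest in cortical markers. The closing observations give their effect.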

Results

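Gene expression was measured by RNA sequencing in the striatum and the substantia nigra of mice after 6-hydroxydopamine (6-OHDA), a toxin that is taken up by dopamine neurons and destroys them. Control mice received phosphate-buffered saline (PBS). A lesion group received 4 µg of 6-OHDA into the striatum with PBS by intraperitoneal injection. A treated group received 6-OHDA and TUG469, an agonist of the free fatty acid receptor GPR40 (gene Ffar1), at 10 mg/kg per day over 3 weeks. The study asked how the GPR40 agonist acts in this model of Parkinson's disease, with the NLRP3 inflammasome as its candidate pathway. Each group had 3 libraries per tissue. Total counts in striatum were 54800811, 42242389 and 52372695 for PBS 1 to 3, 48214331, 52201132 and 54545178 for 6-OHDA 2 to 4, and 61992226, 58351871 and 58492996 for TUG469 1, 2 and 4. In nigra they were 52060845, 53897542 and 57226863 for PBS, 51665747, 61933756 and 59098138 for 6-OHDA, and 57274260, 59378269 and 58923078 for TUG469, in the same order of numbers. Genes of the mitochondrial genome took 9.91% to 11.5% of counts in striatum and 7.24% to 8.81% in nigra.

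Markers of dopamine neurons were examined in the nigra as a check on the lesion. Slc6a3, the dopamine transporter (gene 13162, chromosome 13, 73536128 to 73578672), stood at 57.5 ± 11.1 CPM in PBS libraries, 54.6 ± 11.2 in libraries labelled 6-OHDA and 13.6 ± 2.76 in libraries labelled 6-OHDA plus TUG469 (mean ± SD, n = 3 each). Th, tyrosine hydroxylase, the rate-limiting enzyme of dopamine synthesis (gene 21823, chromosome 7, 142892779 to 142899995), stood at 33.1 ± 6.85, 51.4 ± 9.51 and 17.1 ± 4.16 CPM in the same order. Neither gene was lower in the libraries labelled 6-OHDA than in PBS libraries by edgeR: the log2 change was −0.07 (SE 0.182, adjusted p = 0.877) for Slc6a3 and 0.63 (SE 0.204, adjusted p = 0.242) for Th. In the authors' deposited table, Th passed as higher after 6-OHDA (fold 1.56, adjusted p = 0.0363), while Slc6a3 did not differ (fold −1.05, adjusted p = 0.872). A lesion that destroyed many dopamine neurons would lower these transcripts, so the markers do not show the lesion that the labels name. An uneven lesion and the amount of dopaminergic tissue in each dissection were not tested. Groups of both tissues are named below by their labels: "after 6-OHDA" means in libraries labelled 6-OHDA against PBS, and "under TUG469" in libraries labelled 6-OHDA plus TUG469 against those labelled 6-OHDA. An exchange of these 2 labels in both tissues stays open, and it would turn the direction of each TUG469 comparison with 6-OHDA and make each 6-OHDA comparison with PBS one of 6-OHDA plus TUG469, and each TUG469 comparison with PBS one of 6-OHDA alone. In striatum, Th was at 6.73 ± 1.24, 6.94 ± 0.614 and 6.59 ± 1.09 CPM (n = 3 each), and Slc6a3 was not analysed here.

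**Figure D1:**
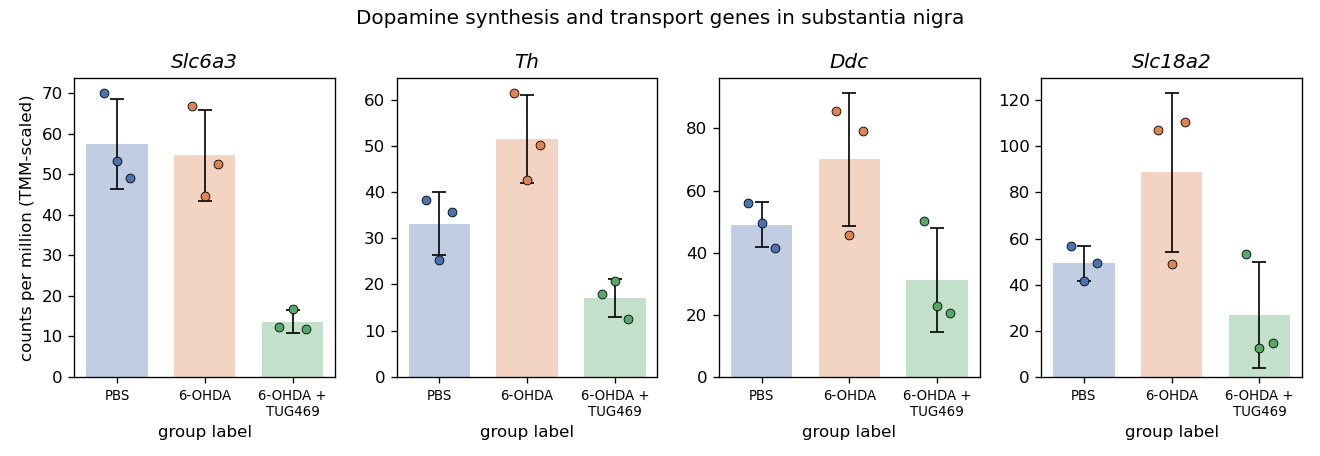
Levels of Slc6a3, Th, Ddc and Slc18a2 in nigra (TMM-scaled CPM) for the PBS, 6-OHDA and 6-OHDA plus TUG469 groups; bars are means of 3 libraries, error bars 1 SD and points single libraries. Slc6a3 averaged 57.5, 54.6 and 13.6 CPM in the 3 groups.

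In striatal libraries labelled 6-OHDA, transcripts of motile cilia, the mark of ependymal cells that line the ventricles, were higher, and transcripts of the mitochondrial respiratory chain were lower. The ependymal list rose as a group, with 9 of 9 members higher, a median log2 change of 1.16 and 9 members past the threshold adjusted over the list alone (0 over all genes tested). Foxj1, the master regulator of motile ciliogenesis (gene 15223, chromosome 11, 116330704 to 116335499), was at 8.94 ± 2.04 CPM in PBS, 16.9 ± 0.885 in 6-OHDA and 13.5 ± 2.25 in TUG469 libraries (n = 3 each). The axonemal dynein gene Dnah11 (gene 13411, chromosome 12, 117877982 to 118199043) had a log2 change of 1.81 (SE 0.299), and the cilium genes Hydin and Tmem212 had changes of 1.92 and 1.83. The oxidative phosphorylation list fell as a group, with 24 of 24 members lower, a median of −0.16 and 5 members past the threshold adjusted over the list alone. The cytochrome c oxidase subunit Cox5b (gene 12859, chromosome 1, 36691487 to 36693388) was at 165 ± 5.20 CPM in PBS and 115 ± 8.45 in 6-OHDA libraries, and Cox5a (gene 12858, chromosome 9, 57517328 to 57532427) at 71.2 ± 2.64 and 56.8 ± 1.78 (n = 3 each). Camera gave adjusted p = 1.45e-21 for the ependymal and 8.95e-14 for the oxidative phosphorylation list, and adjusted p = 0.113 for each with an estimated correlation. With a trend with transcript length and GC content removed, 9 ependymal and 3 oxidative phosphorylation members passed over the list alone. Choroid plexus genes, of another tissue in the ventricles, had 6 of 7 members higher and a median of 1.65 but passed no test (camera adjusted p = 0.114, 0 members over the list alone). Their level was 3.19 log2 units above the PBS mean in 6-OHDA 2 and −0.55 and −0.26 in 6-OHDA 3 and 4, while the ependymal level was 1.37, 1.30 and 1.703.

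Neuroblast transcripts of the ventricle wall, a list added once the ependymal rise was known, were higher in the same libraries for 16 of 18 members (median 0.55, 9 past the threshold adjusted over the list alone). The reactive astrocyte list rose with 16 of 20 members higher and a median of 0.15 (camera adjusted p = 0.00714). Its members past the threshold adjusted over the list alone were Vim, an intermediate filament gene (29.9 ± 4.74 in PBS and 49.7 ± 6.28 CPM in 6-OHDA, n = 3 each), and the complement gene C4b (log2 change 0.51). Glucocorticoid response genes fell as a list with 11 of 11 lower and a median of −0.55 (adjusted p = 0.00024), but 0 members passed the threshold adjusted over the list alone. Zbtb16 had a log2 change of −1.12 and Fkbp5 of −0.64. Blood transcripts, the hemoglobin genes among them, fell with 4 of 4 lower and a median of −1.72 (adjusted p = 0.00485), although reads of near-identical hemoglobin copies such as Hbb-bs make single members uncertain. With an estimated correlation these calls were lost (adjusted p = 0.81 for each), and at the preset correlation other splits of the same 6 libraries gave up to 17 called lists against 5 here. The glucocorticoid and astrocyte calls were also lost without PBS 2 (adjusted p = 0.194 and 0.128, the astrocyte median then −0.00643), the astrocyte call without 6-OHDA 3 (0.0558) and the blood call without PBS 3 (0.062). The glucocorticoid median was −0.298 without PBS 2 and −0.858 without PBS 3, the astrocyte median 0.31 without PBS 3 and the blood median −2.78 without 6-OHDA 4.

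No single striatal gene passed the threshold after 6-OHDA in edgeR (0 of 19115), with 1434 genes at an unadjusted p under 0.05, of which 805 were higher and 629 lower. DESeq2 called 172 genes, and 173 genes passed in the authors' deposited table. The smallest p among higher genes belonged to Maats1, Vwa3a, Cfap65, Ccdc33 and Dnali1, of which at least Cfap65 and Dnali1 encode parts of the cilium. Among lower genes it belonged to Cox5b, Agt, Trir, Ier5l and Cox5a. All of these genes failed the correction. Maats1 (gene 320214, chromosome 16, 38297754 to 38341860) had the largest log2 change of these, 2.06 (SE 0.252, adjusted p = 0.192), and Agt, angiotensinogen, had −1.92 (SE 0.331, adjusted p = 0.214). Groups did not overlap for 11.8% of genes, where chance gives 10%. The count became 2 without PBS 3.

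In the nigra of the libraries labelled 6-OHDA, the respiratory chain and ependymal lists moved the other way. Oxidative phosphorylation genes rose with 24 of 24 higher, a median of 0.14 and 9 members past the threshold adjusted over the list alone, and Cox5a went from 83.8 ± 3.76 to 109 ± 7.45 CPM (n = 3 each). Log2 changes in this comparison went with transcript length across genes, which are not independent replicates (Spearman's rho −0.397). In striatum after 6-OHDA the rho was 0.168, of the opposite sign. The oxidative phosphorylation list is of short transcripts (median 1740 bases). With a trend with length and GC content removed, its median was 0.12 and 2 of its members passed over the list alone. Ependymal genes fell with 9 of 9 lower and a median of −0.90, and Dnah11 went from 4.56 ± 0.456 to 2.04 ± 0.571 CPM. The myelin list rose with 15 of 16 higher and a median of 0.23, including the myelin-associated glycoprotein gene Mag (log2 change 0.29) and the gap junction gene Gjb1 (0.73). Blood transcripts fell with 5 of 5 lower and a median of −1.80, and all 5 passed when adjusted over the list alone. Camera gave adjusted p = 3.84e-09 for oxidative phosphorylation, 4.33e-06 for ependymal, 5.36e-06 for myelin and 2.51e-05 for blood genes. With an estimated correlation the adjusted p was 0.612, 0.612, 0.633 and 0.612. The oxidative phosphorylation median was 0.0776 without 6-OHDA 4, the ependymal median −1.44 without 6-OHDA 2 and the myelin median 0.135 without PBS 2 and 0.37 without PBS 3.

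The dopaminergic list was higher, not lower, in these libraries, with 14 of 20 members higher and a median of 0.37 (camera adjusted p = 0.00137, adjusted p = 0.633 with an estimated correlation). That call was lost without PBS 2 (adjusted p = 0.0549) or without 6-OHDA 2 (0.125, with a median of 0.23). Markers of regions next to the nigra moved too: thalamus genes fell with 8 of 9 lower and a median of −0.60 (adjusted p = 0.00271). Relative to the PBS mean, the thalamus level was −1.25, −0.02 and −1.10 log2 units in 6-OHDA 2, 3 and 4. Striatal projection neuron genes fell with 10 of 13 lower (median −0.19, adjusted p = 0.00313), antigen presentation genes rose with 13 of 13 higher (median 0.18, adjusted p = 0.00313) and meningeal genes rose with 10 of 11 higher (median 0.25, adjusted p = 0.00651). With an estimated correlation the adjusted p of these 4 region and cell lists was 0.612 to 0.674. The thalamus call was lost without PBS 3 (0.051, with a median of −0.36), and the meningeal call without PBS 1 (0.637, with a median of −0.0104) or PBS 3 (0.0793, with 0.0409). Without PBS 2 the meningeal median was 0.89, without 6-OHDA 3 the thalamus median −0.91 and without 6-OHDA 4 the projection neuron median −0.12.

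A single gene fell in the nigra labelled 6-OHDA. Megf9, which encodes a membrane protein with EGF-like repeats (gene 230316, chromosome 4, 70431927 to 70534928), went from 60.8 ± 2.39 CPM in PBS to 38.2 ± 2.23 in 6-OHDA libraries (n = 3 each; log2 change −0.67, SE 0.0602, edgeR adjusted p = 0.0112). Its adjusted p lay between 2.67e-17 and 0.364 in 11 other settings and between 0.00807 and 0.117 with 1 library left out. The call was lost with the trend with transcript length and GC content removed (log2 change −0.52, adjusted p = 0.0581), in a fit of only the compared groups (0.1) and with the replicate number as a block (0.364), and the log2 change was −0.43 by the authors' log2 values. Its transcript is long, at 7924 bases. Cbl, Kif3b, Akap9 and Arfgef3 had the next smallest p among lower genes (log2 changes −0.33, −0.36, −0.37 and −0.62). Cox5a, Tmod1, Ppp1r14a, Mrps24 and Atp5j2 had the smallest among higher genes (0.38, 0.59, 0.71, 0.41 and 0.29). None of these 9 passed the correction (adjusted p = 0.170). At an unadjusted p under 0.05 there were 2819 genes, 1239 higher and 1580 lower, DESeq2 called 437 genes and 430 genes passed in the authors' deposited table. Groups did not overlap for 20.0% of genes against 10% by chance. The count was 0 without PBS 1, 6-OHDA 2 or 6-OHDA 4, 2 without PBS 2 or 6-OHDA 3, and 33 without PBS 3.

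The response to 6-OHDA was then compared between tissues directly. An interaction test over 18749 genes called 29 genes, 17 with a change higher in nigra than in striatum and 12 with a lower one, with 2280 genes at an unadjusted p under 0.05. Cox5a (difference 0.70, SE 0.0878, adjusted p = 0.0112) and Cox5b (0.88) were higher in nigra relative to striatum, as were the respiratory chain genes Ndufc2 (0.52), Ndufs6 (0.51) and Cox8a (0.62). Dnah11 (−2.99, SE 0.422, adjusted p = 0.0128), Maats1 (−3.29) and Vwa3a (−2.27) were lower in nigra relative to striatum. As lists, oxidative phosphorylation differed by a median of 0.28 (camera adjusted p = 6.87e-22, adjusted p = 0.0497 with an estimated correlation) and the ependymal list by −2.18 (3.12e-19, adjusted p = 0.0503 with an estimated correlation). Myelin (0.27), dopaminergic (0.54) and reactive astrocyte genes (−0.27) differed only at the preset correlation (adjusted p = 0.00222, 0.0149 and 0.0149; with an estimated correlation 0.922, 0.623 and 0.623). Megf9 differed by −0.59 with adjusted p = 0.0886. The count of 29 was 7 without PBS 2 of the nigra and 96 without 6-OHDA 2 of the nigra.

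**Figure D2:**
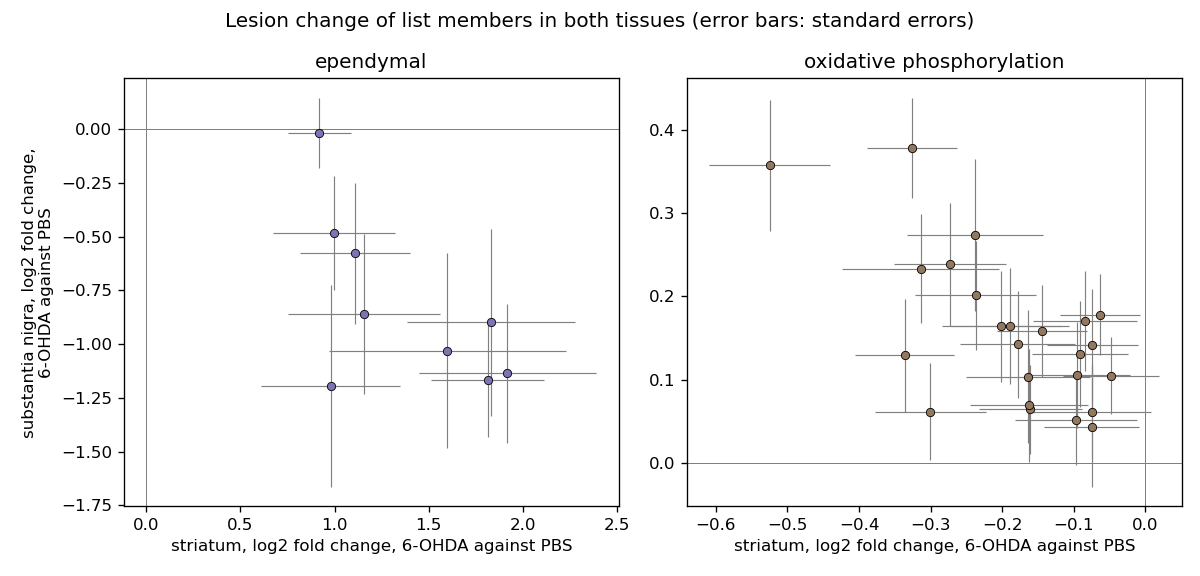
Log2 change after 6-OHDA of 9 ependymal and 24 oxidative phosphorylation genes in striatum (x axis) and nigra (y axis), with bars of 1 SE. The ependymal medians were 1.16 in striatum and −0.90 in nigra, and the oxidative phosphorylation medians −0.16 and 0.14.

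Libraries labelled 6-OHDA plus TUG469 were compared with libraries labelled 6-OHDA. In the striatum, interferon response genes, which cells raise against viruses, rose as a group, with 18 of 19 members higher, a median of 0.76 and 10 past the threshold adjusted over the list alone (0 over all genes). Ifit3 was at 5.77 ± 1.21 CPM in 6-OHDA and 11.7 ± 4.65 in TUG469 libraries (n = 3 each), and Ifit1, Irf7 and Oasl2 had log2 changes of 1.09, 1.22 and 1.04. Antigen presentation genes rose with 13 of 13 higher and a median of 0.50; the class I gene H2-K1 went from 17.4 ± 2.17 to 24.5 ± 1.17 CPM, though near-identical H2 copies share reads. Homeostatic microglia genes rose with 17 of 17 higher and a median of 0.24, such as the integrin gene Itgam (17.99 ± 0.556 to 23.6 ± 1.01 CPM). Endothelial and mural genes rose with 14 of 16 higher and a median of 0.24. Camera gave adjusted p = 1.95e-14, 4.89e-10, 1.24e-07 and 1.29e-06 for these 4 lists, and with an estimated correlation adjusted p = 0.452, 0.452, 0.529 and 0.452. The interferon median was 0.46 without TUG469 2.

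Other striatal lists fell under TUG469. Glucocorticoid response genes fell with 11 of 11 lower and a median of −0.58 (camera adjusted p = 1.53e-06), and Plin4, a lipid droplet coat gene, went from 27.3 ± 16.7 to 3.65 ± 0.435 CPM. Ependymal genes fell with 9 of 9 lower and a median of −0.53 (adjusted p = 0.000877; lost without TUG469 4, 0.0782). Choroid plexus genes fell with 7 of 7 lower and a median of −2.32 (adjusted p = 7.38e-06), and the choroid plexus gene Ttr, a thyroid hormone carrier, was at 49.0 ± 78.9, 541 ± 922 and 5.82 ± 5.01 CPM in PBS, 6-OHDA and TUG469 libraries. The choroid plexus level was 3.19 log2 units above the PBS mean in 6-OHDA 2, and without it the list median was −0.50 (adjusted p = 0.0289). Activated microglia (median 0.14), reactive astrocyte (0.29) and oxidative phosphorylation genes (0.05) rose at adjusted p = 0.00627, 0.0318 and 0.05. The first 2 of these calls were lost without 6-OHDA 4, TUG469 1 or TUG469 4, with adjusted p of 0.0953 to 0.261, and the third without PBS 1, 6-OHDA 2, 6-OHDA 4, TUG469 1 or TUG469 2, with 0.0579 to 0.281. The ependymal median was −0.325 without 6-OHDA 4, −0.28 without TUG469 4 and −0.853 without TUG469 2, and the activated microglia median 0.25 without 6-OHDA 3 and 0.23 without TUG469 2. The reactive astrocyte median was 0.11 to 0.14 without 6-OHDA 4, TUG469 1 or TUG469 4, and that of oxidative phosphorylation 0.0914 without 6-OHDA 3 and 0.0808 without TUG469 4. With an estimated correlation the adjusted p of these 6 lists was 0.529 to 0.581.

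A single striatal gene fell under TUG469. Plekhg4, which encodes a guanine nucleotide exchange factor (gene 102075, chromosome 8, 105369640 to 105382860), went from 36.4 ± 6.81 to 15.5 ± 0.541 CPM (n = 3 each; log2 change −1.24, SE 0.122, edgeR adjusted p = 0.0285). The call was kept in 7 of 12 other settings, with adjusted p from 1.17e-15 to 0.275, and in 2 of 9 fits with 1 library left out. It was lost after quantile normalization (0.092), in a fit of only the compared groups (0.15), with a replicate block (0.275), with the length and GC trend removed (0.0992, log2 change −1.23) and with 2 libraries per group (0.114), and the log2 change was −0.71 by the authors' log2 values. Noxred1, Fam135b, Btaf1 and P4ha1 had the next smallest p among lower genes (log2 changes −1.36, −0.46, −0.45 and −0.58), and Apcdd1, Cd180, Fabp5, Carlr and Gkn3 the smallest among higher genes (0.62, 1.27, 0.35, 1.56 and 1.60). All 9 failed the correction. Cd180, a receptor of the innate immune system, was at 1.52 ± 0.281 CPM in 6-OHDA and 3.65 ± 0.406 in TUG469 libraries. Hspa5, the main chaperone of the endoplasmic reticulum (gene 14828, chromosome 2, 34772090 to 34776529), was at 295 ± 26.4 and 163 ± 5.78 CPM (log2 change −0.85, SE 0.152, adjusted p = 0.322). At an unadjusted p under 0.05 there were 1431 genes, 661 higher and 770 lower, DESeq2 called 61 and 63 genes passed in the authors' deposited table. Groups did not overlap for 14.9% of genes against 10% by chance. The count was 0 without PBS 1, 2 or 3, 6-OHDA 2 or any of the TUG469 libraries.

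In the nigra, dopaminergic transcripts were lower in libraries labelled 6-OHDA plus TUG469 than in libraries labelled 6-OHDA. The dopaminergic list fell with 20 of 20 members lower and a median of −0.75, and 13 members passed when adjusted over the list alone (1 over all genes). Slc6a3 fell by 2.0 on the log2 scale (SE 0.192, edgeR adjusted p = 0.0203). Th had a log2 change of −1.59 (SE 0.209, adjusted p = 0.118), Slc18a2, the vesicular monoamine transporter (gene 214084, chromosome 19, 59260878 to 59296012), −1.73 (SE 0.508) and Ddc, which makes dopamine from L-DOPA (gene 13195, chromosome 11, 11814101 to 11898144), −1.17 (SE 0.334). Slc10a4 (−1.53), Gch1 (−1.21), the transcription factor gene Pitx3 (−1.14) and the nicotinic receptor gene Chrna6 (−0.91) were lower as well. Relative to the PBS mean, the level of the list was 0.64, 0.11 and 0.33 log2 units in 6-OHDA 2, 3 and 4 and −0.22, −0.57 and −0.93 in TUG469 1, 2 and 4. Camera gave adjusted p = 1.39e-36, with an estimated correlation adjusted p = 0.0401, and fry adjusted p = 0.0634. With a trend with transcript length and GC content removed, the median was −0.76. Camera with an estimated correlation, then run on log2 CPM, gave adjusted p = 0.244. Whether the removed trend or the log2 CPM scale ended that call was not tested.

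Other nigral lists that fell under TUG469 were glucocorticoid response (11 of 11 lower, median −0.74, camera adjusted p = 2.78e-09), reactive astrocyte (18 of 23 lower, −0.11, 0.0012), meningeal (10 of 11 lower, −0.38, 0.00558), cortical (8 of 11 lower, −1.15, 0.0139), astrocyte (9 of 14 lower, −0.04, 0.047) and peripheral immune genes (7 of 8 lower, −0.48, 0.047). Thalamus genes rose (9 of 9 higher, median 0.38, adjusted p = 0.0139), as did circadian clock genes (9 of 13 higher, 0.06, 0.047). With an estimated correlation the adjusted p of these 8 lists was 0.482 to 0.542. The level of cortical genes was 1.40 log2 units above the PBS mean in 6-OHDA 3, and without it the cortical median was −0.0317 and the call was lost (adjusted p = 0.321), as it was without TUG469 4 (0.101). The thalamus call was lost without 6-OHDA 2, 6-OHDA 4 or TUG469 4 (0.151, 0.144 and 0.481, with medians of 0.19, 0.25 and −0.15), and the peripheral immune call without 6-OHDA 2 or TUG469 4 (0.24 and 0.288, with medians of −0.21 and −0.25). The astrocyte call was lost without PBS 1, PBS 2, 6-OHDA 3, 6-OHDA 4, TUG469 1 or TUG469 4 (0.0503 to 0.201), and the circadian call without PBS 1, 6-OHDA 2, 6-OHDA 4, TUG469 2 or TUG469 4 (0.0536 to 0.201). The thalamus median was 0.69 and the circadian median 0.11 without 6-OHDA 3, the glucocorticoid median −0.41 without 6-OHDA 4, and the reactive astrocyte median −0.197 to −0.184 without 6-OHDA 3, TUG469 2 or TUG469 4.

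Slc6a3 was the only nigral gene past the threshold between TUG469 and 6-OHDA in edgeR. Its adjusted p was 1.35e-25 to 0.0543 in 11 other settings and 0.0188 to 0.162 with 1 library left out. The call was lost in a fit of only the compared groups (0.0543) and without 6-OHDA 2, 6-OHDA 4, TUG469 1 or TUG469 4 (0.061 to 0.162), and the log2 change was −1.18 by the authors' log2 values. Paqr8, a membrane progestin receptor gene, followed with 314 ± 18.9 CPM in 6-OHDA and 226 ± 9.17 in TUG469 libraries (log2 change −0.48, SE 0.0586, adjusted p = 0.0989), then Th, Chrna6 and the endoplasmic reticulum co-chaperone gene Dnajc3 (−0.40). Among higher genes Actb, Plekhd1, Pllp, Tmem125 and Pipox had the smallest p (0.29, 0.49, 0.50, 0.42 and 0.57). Pllp, a component of myelin, was at 77.7 ± 4.19 and 110 ± 8.46 CPM (adjusted p = 0.370). Hspa5 was at 387 ± 21.5 and 249 ± 20.2 CPM (adjusted p = 0.401). At an unadjusted p under 0.05 there were 1615 genes, 759 higher and 856 lower, DESeq2 called 97 and 91 genes passed in the authors' deposited table. In the authors' deposited table, Th had a fold of −3.01 with an adjusted p of 1.24e-12 between TUG469 and 6-OHDA. Groups did not overlap for 14.4% of genes against 10% by chance. The count was 0 without 6-OHDA 2, 6-OHDA 4 or TUG469 4, 3 without TUG469 1 and 4 without PBS 2.

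No gene differed between tissues in its response to TUG469 by the edgeR interaction test (0 of 18749, with 700 at an unadjusted p under 0.05), and the count was 2 without TUG469 1 of the nigra. Th differed by −1.51 (SE 0.289, adjusted p = 0.759). As lists, interferon (median difference −0.62, camera adjusted p = 3.57e-11), antigen presentation (−0.42, 1.19e-09), dopaminergic (−0.56, 5.46e-09), reactive astrocyte (−0.41, 8.62e-07), endothelial (−0.20, 1.49e-05), meningeal (−0.75, 0.000166), homeostatic microglia (−0.17, 0.000887), cortical (−1.19, 0.00215) and oxidative phosphorylation genes (−0.06, 0.0122) were lower in nigra relative to striatum. Choroid plexus (2.295, 6.7e-07), ependymal (0.80, 1.46e-05) and circadian genes (0.11, 0.00855) were higher. The adjusted p with an estimated correlation was 0.0611 for dopaminergic and reactive astrocyte, 0.15 for antigen presentation, 0.17 for interferon and 0.17 to 0.573 for the other lists. Interferon genes were therefore not shown to respond differently in the 2 tissues once the correlation between genes was estimated.

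**Figure D3:**
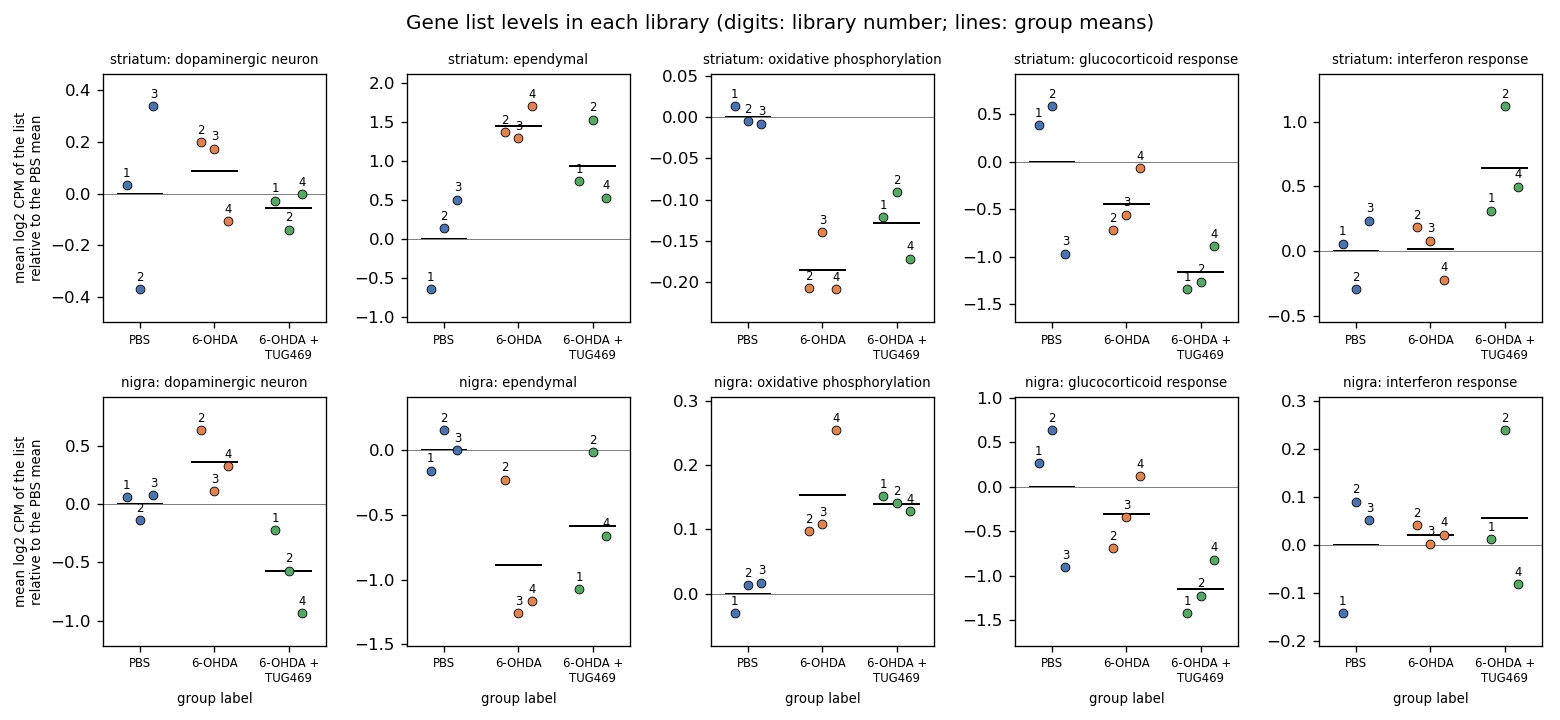
Level of the dopaminergic, ependymal, oxidative phosphorylation, glucocorticoid and interferon lists in each library (mean log2 CPM of the list minus the PBS mean), with striatum above and nigra below; digits are library numbers and lines group means. In nigra the dopaminergic level was 0.11 to 0.64 in the 6-OHDA libraries and −0.93 to −0.22 in the TUG469 libraries.

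Changes after 6-OHDA and changes under TUG469 share the 6-OHDA libraries, which by itself makes them opposite. Across genes, which are not independent replicates, the correlation of the 2 changes was −0.386 in striatum and −0.393 in nigra. Unchanged groups simulated with the same shared libraries gave mean correlations of −0.474 and −0.502 over 100 draws. The covariance was −0.0318 in striatum against a simulated mean of −0.0327, and 50 of 100 draws were as negative. In nigra it was −0.0323 against −0.0304, and 31 of 100 draws were as negative. Of the 1434 striatal genes with an unadjusted p under 0.05 after 6-OHDA, 79.3% had the opposite sign under TUG469. Simulated draws gave a mean of 93.4% (81.9% to 100%). Of the 2819 nigral genes 61.5% had the opposite sign, against a simulated mean of 89.6% (77.2% to 97.8%). Both shares lay below every draw. The draws ranked genes by a spread that included the simulated changes themselves, unlike the edgeR p, which raises the simulated shares. These shares therefore cannot decide whether signs turned more or less often than in unchanged groups. By the covariances, a reversal of the 6-OHDA changes beyond that of the shared libraries was not detectable.

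Libraries labelled 6-OHDA plus TUG469 were finally compared with PBS libraries, a comparison of 6-OHDA alone with PBS if the labels were exchanged. In the striatum, glucocorticoid response genes fell with 11 of 11 lower, a median of −1.09 and 10 past the threshold adjusted over the list alone (0 over all genes). Zbtb16 was at 44.2 ± 22.7 CPM in PBS and 13.6 ± 3.8 in TUG469 libraries. Interferon (19 of 19 higher, median 0.59, 11 past the threshold adjusted over the list alone), antigen presentation (13 of 13 higher, 0.42, 6) and ependymal genes (9 of 9 higher, 0.79, 5) rose. Reactive astrocyte genes rose with 15 of 20 higher, a median of 0.51 and 8 past the threshold over the list alone, including Vim (log2 change 0.76), C4b (0.80) and Serping1 (0.66). Homeostatic microglia (15 of 17 higher, median 0.21) and activated microglia genes (16 of 20 higher, 0.24) rose, while oxidative phosphorylation (23 of 24 lower, −0.13) and blood genes (4 of 4 lower, −2.67) fell. Camera gave adjusted p from 1.78e-13 for glucocorticoid response to 8.69e-05 for activated microglia genes over these 9 lists, and adjusted p = 0.31 for each with an estimated correlation. Choroid plexus, circadian, endothelial and striatal projection neuron genes passed at 0.0349 to 0.0448, with 0.444 to 0.615 under an estimated correlation. The choroid plexus call was lost without PBS 1 (0.164), the circadian call without PBS 1, PBS 2, TUG469 1 or TUG469 4 (0.0881 to 0.282; its median of −0.0681 was 0.0152 without PBS 2), the endothelial call without PBS 2, PBS 3, TUG469 1 or TUG469 2 (0.068 to 0.221) and the neuronal call without PBS 2, TUG469 1 or TUG469 4 (0.173 to 0.474). Without PBS 2 the homeostatic microglia median was 0.12, the reactive astrocyte median 0.216, the neuronal median −0.0331 (−0.16 with it) and the endothelial median 0.0151 (0.13 with it). Without PBS 3 the interferon median was 0.94, antigen presentation 0.845, endothelial 0.28 and circadian −0.15. Without TUG469 2 the ependymal median was 0.45, blood −4.92, neuronal −0.299 and endothelial 0.0806. The neuronal and circadian medians were −0.0816 and −0.0402 without TUG469 1, and −0.0916 and −0.0115 without TUG469 4.

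No striatal gene passed the threshold between TUG469 and PBS in edgeR (0 of 19115; lowest adjusted p = 0.0797, for Plekhg4 with a log2 change of −1.10). Lgals3, a galectin of activated microglia (log2 change 1.79), Cd180 (1.52) and Hspa5 (−1.04) were among the genes with the next smallest p (adjusted p = 0.128 each). At an unadjusted p under 0.05 there were 2395 genes, 1216 higher and 1179 lower, DESeq2 called 327 and 318 genes passed in the authors' deposited table. Groups did not overlap for 18.5% of genes against 10% by chance. The count was 46 without PBS 3 and 1 without 6-OHDA 3 or 6-OHDA 4.

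In the nigra, 364 genes differed between TUG469 and PBS, 79 higher and 285 lower. Opalin, a myelin protein of oligodendrocytes (gene 226115, chromosome 19, 41061959 to 41077113), rose from 20.8 ± 7.35 to 51.8 ± 6.81 CPM (n = 3 each; log2 change 1.32, SE 0.224, edgeR adjusted p = 0.0270), the largest rise by the naming rule. Ofd1, Gkn3, Sgk2, Cyp3a13, Ppp1r14a, Tmod1, Slc26a10, Sfrp5 and Tmem98 followed with log2 changes of 1.14 to 0.87. Plin4 (gene 57435, chromosome 17, 56100587 to 56109948) fell from 74.8 ± 50.4 to 6.91 ± 0.962 CPM (log2 change −3.44, SE 0.609, adjusted p = 0.0308). Cdkn1a, a cell cycle inhibitor (gene 12575, chromosome 17, 29090979 to 29100722), fell from 37.3 ± 20.5 to 7.72 ± 1.11 CPM (−2.27, SE 0.388, adjusted p = 0.0270). Slc6a3 fell by 2.08 (SE 0.192, adjusted p = 0.00407), and the opioid receptor gene Oprm1 from 6.36 ± 1.09 to 2.64 ± 0.461 CPM. Zbtb16, Fbxw23, Zbtb20, Ccdc3 and Fam167a were also among the 10 largest falls (−1.89 to −0.99). Hspa5 (−0.66, adjusted p = 0.0415) and the unfolded protein response factor gene Xbp1 (−0.54, adjusted p = 0.0333) fell, and the clock output gene Dbp rose by 0.70. Th had a log2 change of −0.96 (adjusted p = 0.0505).

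As lists in the same comparison, glucocorticoid response (11 of 11 lower, median −1.12, 8 past the threshold adjusted over the list alone and 2 over all genes), dopaminergic (17 of 20 lower, −0.57, 8 and 1) and blood genes (5 of 5 lower, −2.30) fell. Myelin (14 of 16 higher, median 0.31, 8 and 2) and oxidative phosphorylation genes (24 of 24 higher, 0.13, 5 and 0) rose. With a trend with transcript length and GC content removed, the myelin median was 0.32 (SD over members 0.331; 0.31 and 0.337 before) and the oxidative phosphorylation median 0.0952 (0.081; 0.135 and 0.0781 before). Members past the threshold over the list alone then numbered 2 for myelin (7 before on genes of known length) and 0 for oxidative phosphorylation (5 before), and the myelin changes were thus not smaller with the trend removed. Camera gave adjusted p = 4.28e-09, 1.2e-08, 1.41e-06, 5.68e-07 and 2.64e-06, and with an estimated correlation adjusted p = 0.353, 0.353, 0.353, 0.43 and 0.43. Reactive astrocyte, astrocyte, hypothalamic, ependymal and striatal projection neuron genes fell and antigen presentation genes rose at adjusted p of 0.00687 to 0.0173, and 0.353 to 0.637 with an estimated correlation. Of these, the antigen presentation call was lost without PBS 1 or TUG469 2 (0.163 and 0.104), the projection neuron call without PBS 1 or TUG469 4 (0.0786 and 0.0724), the ependymal call without PBS 2, TUG469 1 or TUG469 4 (0.0523 to 0.222), the hypothalamic call without PBS 3 (0.0973) and the astrocyte call without TUG469 4 (0.088). The ependymal median of −0.67 was −0.41 without TUG469 1, −1.05 without TUG469 2 and −0.42 without TUG469 4, and the hypothalamic median of −0.77 was −0.48 without PBS 1, −2.61 without TUG469 1 and −1.31 without TUG469 4. The projection neuron median of −0.14 was −0.0678 without PBS 1, the reactive astrocyte median of −0.21 was −0.13 without TUG469 1, and the glucocorticoid median was −0.67 without PBS 2. At an unadjusted p under 0.05 there were 3881 genes, DESeq2 called 1560 and 1505 genes passed in the authors' deposited table. Groups did not overlap for 24.0% of genes against 10% by chance. The 364 genes became 8 without PBS 1, 9 without TUG469 2, 83 without TUG469 1, 147 without 6-OHDA 2, 165 without 6-OHDA 4, 166 without PBS 2 and 186 without 6-OHDA 3. The count was 39 in a fit of only the compared groups and 13 with the replicate number as a block. It was 73 once a trend with transcript length and GC content was removed and 722 with the thalamus marker level as a covariate. Called genes went with transcript length: the median length was 7009 bases for lower, 2602 for higher and 3118 for all tested genes.

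The inflammasome genes named by the study gave no call in either tissue. Nlrp3 (gene 216799, chromosome 11, 59541569 to 59566955) was at 0.937 ± 0.113, 0.946 ± 0.165 and 1.01 ± 0.0405 CPM in striatal PBS, 6-OHDA and TUG469 libraries and at 0.867 ± 0.0792, 0.563 ± 0.164 and 0.681 ± 0.269 in nigra (n = 3 each). Its log2 change was 0.01 after 6-OHDA and 0.09 under TUG469 in striatum (adjusted p = 0.996 and 0.944) and −0.62 and 0.28 in nigra (0.401 and 0.867). Casp1, the inflammasome protease (gene 12362, chromosome 9, 5298517 to 5307281), was at 0.557 ± 0.147, 0.902 ± 0.165 and 0.534 ± 0.113 CPM in nigra, with log2 changes of 0.69 and −0.76 (adjusted p = 0.312 and 0.557). Pycard, the inflammasome adaptor, and the cytokine gene Il18 had adjusted p of 0.474 and 0.983 after 6-OHDA in striatum. Ffar1 and Il1b were not analysed here. The inflammasome list held 12 tested members in striatum and 13 in nigra, with 0 past the threshold adjusted over the list alone. Its camera adjusted p was 0.252, 0.942 and 0.146 in striatum and 0.625, 0.904 and 0.782 in nigra for 6-OHDA, TUG469 against 6-OHDA and TUG469 against PBS. In striatum under TUG469 its median was −0.01 and its mean 0.02, and in nigra under TUG469 0.04 and −0.06. In nigra against PBS both were −0.04 while the test pointed up. At about 1 CPM these genes had 16 to 130 reads per library in striatum for Nlrp3, Pycard and Casp1, which limits what could be detected.

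Gfap and Aif1 passed the edgeR threshold in none of the comparisons. Gfap, the astrocyte filament (gene 14580, chromosome 11, 102887336 to 102897200), was at 87.4 ± 39.8, 103 ± 23.6 and 127 ± 29.5 CPM in striatum (adjusted p = 0.932 after 6-OHDA and 0.876 under TUG469). The microglial gene Aif1 had log2 changes of 0.26 and 0.29 in striatum (adjusted p = 0.788 and 0.724) and 0.08 and 0.34 in nigra (0.899 and 0.775). Of 32 lists, 11 passed no camera test in any comparison: NLRP3 inflammasome, cytokine and NF-kB, direct and indirect pathway neurons, immediate early, axon injury and integrated stress, NRF2, fatty acid receptor, oligodendrocyte precursor, pan-neuronal and nigral GABA genes. Their medians lay between −0.37 and 0.18, and the lowest camera adjusted p was 0.0556.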

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

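Of the tests here, those of exchanged labels, of the thalamus share and of a trend with transcript length and GC content were chosen after the result was seen; those of neuroblast transcripts and library size were chosen once the pattern was known but written before their own values were seen, and the other splits were planned. Library size was first compared as overlap of totals, which decided nothing, and thinning of the counts took its place.

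The change after 6-OHDA differed between striatum and nigra in 29 genes and in the oxidative phosphorylation list, whose median was 0.28 log2 units higher in nigra. The list passed narrowly by camera with an estimated correlation (adjusted p = 0.0497). That call was not kept on log2 CPM with a trend with transcript length and GC content removed. Among the named genes, the difference (nigra minus striatum) was 0.70 for Cox5a, 0.88 for Cox5b, 0.92 for the mitochondrial ribosome gene Mrps24, 1.24 for Ier5l and 0.76 for Trir. It was −2.99 for Dnah11, −3.29 for Maats1 and −2.27 for Vwa3a. These genes were picked out because the test of the difference itself passed its threshold. Of 30 splits of the libraries within each tissue, 1, the real one, gave 29 genes and the highest other gave 6. That is the smallest share 30 splits can give. A count of 29 was thus rare among these splits, which are too few to exclude chance. The count was 7 without nigral PBS 2 and 7 after quantile normalization, and the splits were not run for those fits.

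Dopaminergic transcripts were lower in nigral libraries labelled 6-OHDA plus TUG469, while those labelled 6-OHDA kept the PBS level of Slc6a3. An exchange of these labels in the nigra alone is argued against only if same-numbered libraries come from 1 animal, which the labels do not say. Here 6 of 6 striatal libraries matched the nigral library of their own group and number best. The correlations were 0.0643 to 0.127, against at most 0.107 for the other group, and the margin was small for TUG469 4 (0.121 against 0.107). A different share of thalamus is argued against: with the level of 9 thalamus genes, all measured in nigra, as a covariate, the list median was −0.70 (−0.75 without it) and Slc6a3 had a log2 change of −1.92 (SE 0.184, adjusted p = 0.0201). An exchange in both tissues cannot be told apart from correct labels, because Slc6a3 changed by −0.0737 between libraries labelled 6-OHDA and PBS and the labels carry no independent mark of the toxin. The amount of dopaminergic tissue in each dissection and an effect of TUG469 or of an uneven lesion were not tested and stay open.

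Ependymal transcripts were higher and respiratory chain transcripts lower in striatal libraries labelled 6-OHDA than in PBS, with the opposite in nigra. A trend with transcript length and GC content is argued against for the ependymal genes, whose striatal median was 1.16 with the trend removed and which kept 9 members past the threshold adjusted over the list alone, and as the whole cause for oxidative phosphorylation, whose difference between tissues was 0.203 afterwards (0.282 before; 11 members past the threshold against 17). Within each tissue its members past the threshold over the list alone went from 9 to 2 in nigra (median 0.14 to 0.12) and from 5 to 3 in striatum (−0.16 to −0.12), so the trend may hold part of that change. For the difference between tissues, camera with an estimated correlation gave the list unadjusted p = 0.00155 before. With the trend removed, and run on log2 CPM, it gave unadjusted p = 0.0024, which does not pass once adjusted over the lists. More ventricle wall in the striatal 6-OHDA dissections is a candidate source of the ependymal part. Neuroblast transcripts of the same wall had a median log2 change of 0.55. A bootstrap over the 18 genes gave an interval of 0.178 to 1.01. That interval does not measure the spread between libraries, and genes are not independent replicates. Of these genes 16 of 18 were higher and 9 passed over the list alone (p = 0.0225 by camera with an estimated correlation), among them Dlx1 (1.29), Dcx (0.57), Top2a (1.77) and Mki67 (1.7). All 18 are also measured in striatum, Sp9, Sox11 and Tubb3 stand in other lists, and the most abundant, Tubb3 (229 CPM in PBS and 238 in 6-OHDA) and Tubb2b (132 and 150), changed by 0.06 and 0.18, and choroid plexus genes (median 1.65, 6 of 7 higher, camera adjusted p = 0.114) were above the PBS mean in 1 of 3 6-OHDA libraries, 6-OHDA 2 (by 3.19 log2 units), so this candidate and growth of these cells after the lesion both stay open. For the ependymal fall in nigra and the respiratory chain genes no source was tested.

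Most of the genes that differed between TUG469-treated and PBS nigra were lower. A difference in library size is argued against, since thinning every library to the smallest total left 359 genes, 280 of them lower, and 338 of the 364 remained. A trend with transcript length and GC content may account for the excess of lower genes: with it removed, 73 genes were called, 37 higher and 36 lower, against 414 (320 lower) on the same genes before, and 60 were shared. The median log2 change of the 320 lower genes went from −0.35 to −0.215 (median SE 0.0631 and 0.0595), and that of the 94 higher genes from 0.46 to 0.436. The correlation across genes of the fold change with length was −0.41 by Spearman's rho, and genes are not independent replicates. Of the 10 splits of these 6 libraries the real one gave 364 genes and the highest other 292, and 10 splits are too few for a share under 0.05; what produced the trend was not tested.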

How the results depend on the processing

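RLE scaling, the marker-level covariates, the removal of the length and GC trend and the striatum without its libraries lowest in cortical markers (2 libraries per group) were chosen after the data were seen. No called gene changed sign and no called list changed camera's direction, but the medians of 5 lists changed sign where their call was lost: thalamus in nigra under TUG469 (0.38 to −0.15 without TUG469 4), meningeal in nigra after 6-OHDA (0.25 to −0.0104 without PBS 1), reactive astrocyte in striatum after 6-OHDA (0.15 to −0.00643 without PBS 2) and, for TUG469 against PBS in striatum, circadian (−0.0681 to 0.0152 without PBS 2 and 0.0318 with the cortex covariate) and endothelial genes (0.133 to −0.00996 with 2 libraries per group). The nigral covariance in excess of shared libraries, −0.00188, was 0.00106 to 0.00131 with limma, a move under its simulated SD of 0.00974. Among named genes, 4581 of the values under other settings kept their side of the threshold, 189 gained a call and 125 lost one; with 1 library left out 3793 kept it, 43 gained and 169 lost. RLE factors kept 57 of 57 list calls and brought those in nigra after 6-OHDA from 9 to 11. DESeq2 called more genes than edgeR in all 6 comparisons. Depth was lowest in striatal PBS 2 (42242389 counts), and genes near 1 CPM rest on few reads. The cause of the differences was not tested unless named. Summing rows per gene symbol had no effect to test, since symbols are unique.

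With an estimated correlation camera called 0 lists in 5 comparisons and 1 in nigra under TUG469 (preset 5, 10 and 13 in striatum for 6-OHDA, TUG469 and TUG469 against PBS, and 9, 9 and 11 in nigra). Fry called 1, 0 and 0 in striatum and 0, 0 and 1 in nigra. In nigra under TUG469, limma on FPKM with a pseudocount of 1 or 0.1, quantile normalization and the authors' log2 values each called 4 lists, and 3 were left without the length trend, as many as by the same test on log2 CPM before its removal. For striatal 6-OHDA genes, the authors' log2 values gave 1 gene, DESeq2 172, the cortex covariate 16 and 2 libraries per group 4 genes and 14 lists. For striatal TUG469 genes, quantile normalization, the fit of 2 groups, the removed trend and 2 libraries per group gave 0, and DESeq2 61. For TUG469 against PBS in striatum, the fit of 2 groups gave 1, DESeq2 327, the cortex covariate 13 and 2 libraries per group 10.

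In nigra, 6-OHDA genes numbered 0 in the fit of 2 groups or with the trend removed, and 437 by DESeq2. TUG469 genes numbered 0 in the fit of 2 groups, 97 by DESeq2 and 2 with the thalamus covariate. For TUG469 against PBS (79 higher, 285 lower), limma gave 205 (93 and 112) with a pseudocount of 1 and 204 (92 and 112) with 0.1, quantile normalization 272 (108 and 164), the fit of 2 groups 39, DESeq2 1560 (491 and 1069), the thalamus covariate 722 (151 and 571) and the removed trend 73 (37 and 36). The 29 genes that differed between tissues became 18 with no filter, 9 with a pseudocount of 0.1, 7 after quantile normalization and 15 with the trend removed.

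With 1 library left out, striatal gene counts ranged from 0 to 2 (6-OHDA), 0 to 1 (TUG469) and 0 to 46 (TUG469 against PBS), and lists from 4 to 15, 8 to 16 and 11 to 19. Nigral gene counts ranged from 0 to 33, 0 to 4 and 8 to 527, and lists from 8 to 11, 6 to 11 and 9 to 12. The difference between tissues ranged from 7 to 96 genes for 6-OHDA and 0 to 2 for TUG469. The covariance in excess of that of shared libraries ranged from −0.00427 to 0.0137 in striatum and −0.0161 to 0.014 in nigra.

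The replicate numbers were checked for pairing: within a tissue, deviations of same-numbered libraries correlated between −0.264 and 0.417, over 0.1 in 6 of 12 pairs. Differently numbered libraries were not compared, so pairing of groups by number was neither shown nor excluded. Across tissues each library correlated best with its own number within its group in 9 of 9 cases (0.0156 to 0.218), a hint from the data and not from the design. With the number as a replicate block, striatum gave 9 lists for 6-OHDA and 0 genes for TUG469. Nigra gave 0 genes for 6-OHDA, 3 genes and 14 lists for TUG469 and 13 genes for TUG469 against PBS. With library group and number as the block for mouse, 62 genes differed between tissues after 6-OHDA.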

Other observations

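The test of the glucocorticoid level was chosen after the result was seen; the chaperone tests were written before it, on genes other than those that prompted them, and the splits were planned.

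Most endoplasmic reticulum chaperone genes, which fold secreted proteins, had negative log2 changes under TUG469 in both tissues. Hspa5, Dnajc3 and Xbp1 drew attention to them, and 25 other members were tested, of which none passed over all genes in edgeR (lowest adjusted p = 0.401 in nigra and 0.533 in striatum). In nigra 23 of 25 were lower with a median log2 change of −0.15, and 10 passed the threshold adjusted over the list alone, including Sdf2l1 (−1.16), Manf (−0.60), Pdia4 (−0.60) and Creld2 (−0.59). In striatum 22 of 25 were lower with a median of −0.18, and 8 passed, including Sdf2l1 (−0.74), Pdia4 (−0.57) and Calr (−0.50). Camera with an estimated correlation gave p = 0.0486 in nigra and p = 0.0593 in striatum, so a fall of the class is a hypothesis that these libraries leave undecided. After 6-OHDA alone the medians were 0.01 in nigra and −0.03 in striatum.

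The glucocorticoid response level varied between libraries of 1 group, and alike in both tissues. Among PBS libraries 1, 2 and 3 it was 0.39, 0.58 and −0.97 log2 units from the PBS mean in striatum and 0.27, 0.64 and −0.90 in nigra. Deviations from the group mean correlated between tissues over the 9 libraries with r = 0.985 (exact permutation p = 0.00463, the smallest that 216 permutations can give) and rho = 0.933 (exact permutation p = 0.00463). Without the 2 libraries farthest from the median r was 0.962, and over 32 lists the Benjamini-Hochberg adjusted exact p was 0.148. A list at the smallest possible p can pass that adjustment only if several lists reach it, so the adjusted value could not decide. The correlation is in line with a level shared by striatum and nigra of 1 animal, such as stress or time of day at killing, but the labels do not say that same-numbered libraries come from 1 animal, and it cannot be told apart from a shared handling batch.

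Other splits of the 6 libraries of a comparison were refitted, and 10 splits are too few for a share under 0.05. In striatum, real and highest other gene counts were 0 and 18 for 6-OHDA, 1 and 0 for TUG469 and 0 and 1 for TUG469 against PBS. In nigra they were 1 and 1, 1 and 1, and 364 and 292. For lists they were 5 and 17, 10 and 18 and 13 and 15 in striatum and 9 and 12, 9 and 9 and 11 and 12 in nigra. In order, 10, 1, 10, 2, 2 and 1 of the 10 splits gave as many genes and 10, 7, 3, 7, 2 and 3 as many lists, the real one included. Camera at its preset correlation thus called at least as many lists for some mixed split of each comparison. For the difference between tissues under TUG469, where 0 genes were called, 30 of 30 splits gave as many.

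Among the other splits of the striatal PBS and 6-OHDA libraries, the highest counts were 18 genes, against 0 in the real one, and 17 lists, against 5, not shown to come from 1 split. Such counts point to a structure of the samples. The leading principal component of striatum held 31.0% of the variance and was highest in PBS 2 (44.8), 6-OHDA 4 (34.6) and TUG469 2 (14.4). The same libraries were the lowest of their groups in markers of cortex and hippocampus, at −1.69, −1.38 and −0.67 log2 units from the striatal mean.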
